A study of Mus musculus with 6 samples.

How the data were processed

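RNA was sequenced from kidney proximal tubule cells of adult female C57BL/6 mice that had been ovariectomized at postnatal day 21. The tubule cells were taken from dissociated kidney cortex with magnetic beads against prominin-1, a surface protein of the proximal tubule, per the labels' protocols. The kidneys were uninjured. There were 3 control libraries (Ctr) and 3 libraries from mice lacking the receptor for insulin-like growth factor 1 (Igf1r) in the proximal tubule (KO). The labels call the 3 libraries of a group biological replicates.

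The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the library's mapped total), with 2 decimals, for 52405 Ensembl gene identifiers in the 6 libraries. Libraries were made with a strand-preserving kit (NEBNext Ultra II Directional), per the labels' protocols. STAR 2.6.0c, RSEM and DESeq2 1.28.1 are named in the submitters' processing notes, with no roles given. The genome build, the annotation and whether reads were counted by strand are not given in the sources used here. Coordinates are those of GENCODE M21 (GRCm38), matched by gene identifier, which found 52147 of the identifiers (99.5%). FPKM is relative to each library's own total, so a change in a few abundant genes shifts all others. Where transcripts of different genes share sequence, the authors' quantification divided the reads by an estimate, and the split between near-identical copies is uncertain.

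The files hold no read counts. Genes with few reads take values in steps of 1 fragment, and these steps give each library's approximate depth. It was 11000000, 11400000 and 11600000 fragments in Ctr replicates 1, 2 and 3 and 12800000, 11000000 and 10000000 in KO replicates 1, 2 and 3. The deepest library held 1.29 times the fragments of the shallowest, and an estimate from pairs of libraries gave 1.28. No 2 libraries held identical values.

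Values were used as deposited, as log2(FPKM + 1). A fold change on this scale understates the change of genes with low FPKM. The 12770 genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Igf1r was also given an exact two-sided permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. The half-width of the 95% interval of a log2 change had a median of 0.29 over the genes tested.

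Before the data were examined, 47 gene lists were fixed from textbook knowledge: segments of the proximal tubule, transport and metabolism, Igf1r and stress signalling, sex-biased kidney genes, tissue dissociation, and other cell types of the kidney. The 44 lists with at least 5 tested genes were tested with limma's camera, which sets a list against all other genes, at a preset correlation between genes of 0.01, with adjustment over the 44 lists. Too few genes were tested for the lists of lymphocytes (2 genes), urothelium (1 gene) and adipocytes and adrenal (1 gene). Alongside stood camera with a correlation estimated from the 6 libraries, and fry, which tests whether the genes of a list move, on balance, one way. The estimated correlation leaves camera far fewer degrees of freedom. It ran from -0.025 to 0.701 over the lists past the threshold at the preset 0.01. For ribosomal proteins it was 0.562, for the late proximal tubule 0.561 and for fatty acid oxidation 0.552. Where it lies far above 0.01, the p at the preset correlation overstates the evidence. Genes past the threshold were also counted adjusted over the list alone. That adjustment makes no allowance for the 44 lists, so some such passes can arise by chance.

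Named genes were chosen by a rule fixed before the data were examined. It takes Igf1r, then in each direction the 12 genes with the largest change among those past the threshold whose groups do not overlap, filled up to 6 by the smallest p where fewer pass. It adds up to 4 members per list (3 for other cell types and dissociation) by the smallest p. The rule left out pseudogene, Gm and mitochondrially encoded symbols at the first step. It named 162 genes, of which 70 are printed here. Gm2446, Gm2436, Gm37376, Malat1 and mt-Rnr2, and the genes that set the libraries numbered 1 apart, were chosen after their values were seen.

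Replicates of both groups carry the numbers 1 to 3 in the labels, which do not say what a number stands for. Deviations from the group means, over genes, correlated by 0.63, 0.29 and 0.37 between the Ctr and KO libraries numbered 1, 2 and 3. All 3 lay above 0.1, so the numbers were taken to pair the libraries, from the data and not from the labels. Ctr replicate 3 and KO replicate 2 correlated by 0.30 as well, and Ctr replicate 2 and KO replicate 3 by 0.15. Both lay above 0.1 too, so the correlations mark only the libraries numbered 1 as a pair. The pairing of the libraries numbered 2 and 3 is an assumption. The fit without a term for the number stayed the main one, with the fit that includes it (the replicate block) as an alternative.

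The gene test was tried on simulated data, with the spread of these 12770 genes, in 20 simulations of KO against Ctr. In each, 200 genes were changed and a list of 30 other genes was moved by 0.3 on the log2 scale. The gene test recovered 47.8% of the genes changed 1.5-fold, 85% at 2-fold and 98.3% at 4-fold. On average 6.4% of its calls were false, which means outside both the changed genes and the moved list. With the spread of the blocked fit it recovered 77.9% at 1.5-fold and 98.2% at 2-fold. These simulations held no replicate effect, drew genes independently and were tested without the block. The latter rates are therefore not those of the blocked test. Alternatives were other pseudocounts, filters, scalings and limma settings, the replicate block, and each library left out in turn. Leaving out both libraries numbered 1, a term that sets these 2 libraries against the rest, removal of a trend with transcript length, and an estimated correlation in the blocked fit were added after the data had been seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.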

Results

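The comparison asked how gene expression in the proximal tubule of uninjured, ovariectomized female mice differs when these tubule cells lack Igf1r, a tyrosine kinase receptor for insulin-like growth factors. Prominin-1-positive cells of 3 Ctr and 3 KO kidney cortices were profiled by RNA-seq. Between 20920 and 21751 genes were above 0 in a library. Mitochondrially encoded genes took 20 to 24.4% of the summed FPKM and ribosomal protein genes 4.13 to 4.83%. The first principal component held 50% of the variance and set Ctr replicate 1 (-30.6) and KO replicate 1 (-25.1) apart from the other 4 libraries (11.4 to 15.6).

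Igf1r (ENSMUSG00000005533, GRCm38 chromosome 7, 67952827 to 68233668) was lower in all 3 KO libraries. Its FPKM was 18.7, 15.3 and 22.7 in Ctr replicates 1, 2 and 3 and 4.78, 7.67 and 5.08 in KO replicates 1, 2 and 3. The means were 18.9 ± 3.72 and 5.84 ± 1.59 (SD, n = 3 each), 3.24-fold lower in KO. The log2 change was -1.55 (SE 0.20), and the exact two-sided permutation test gave p = 0.1, the smallest it can give for 3 against 3. With limma the change did not pass over all genes tested (adjusted p = 0.267), and it passed when adjusted over the list alone, that of insulin-like growth factor and insulin signalling (adjusted p = 0.00321). A deletion of part of the gene can leave a shortened transcript that still counts toward its FPKM. The libraries also held transcripts of other tubule segments (levels below). The source of the Igf1r FPKM left in KO was not tested.

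Esr1, the oestrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), rose in KO. Its FPKM was 0.72, 0.98 and 0.74 in Ctr and 9.14, 18.1 and 18.1 in KO, means of 0.813 ± 0.145 and 15.1 ± 5.18 (SD, n = 3 each), 18.6-fold higher. Its log2 change was 3.10 (SE 0.25, limma adjusted p = 0.0284). The other 2 genes past the threshold were a pair of unprocessed pseudogenes on chromosome 12 that moved in opposite directions. Gm2446 (ENSMUSG00000112690, 55217176 to 55226072) was listed at 0 in all 3 Ctr libraries and at 6.61, 4.60 and 7.17 in KO (limma adjusted p = 0.00945). Gm2436 (ENSMUSG00000112022, 55142109 to 55151007) fell from 6.17 ± 0.104 to 0.403 ± 0.350 (SD, n = 3 each, log2 change -2.39, SE 0.20, limma adjusted p = 0.0284). The annotated transcripts of the pair were identical over 771 of 771 aligned bases, so the division of reads between them is uncertain. Their summed FPKM was 6.17 ± 0.10 in Ctr and 6.53 ± 1.3 in KO (SD, n = 3 each).

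In all, 2 genes were higher and 1 was lower in KO by limma among 12770 tested, while 448 genes had an unadjusted p under 0.05 against 638.5 expected by chance. The values of the groups did not overlap for 8.6% of genes, where chance gives 10%. With the replicate block 720 genes had an unadjusted p under 0.05, above that expectation, and 4 genes passed, the 3 above and Gm37376 (log2 change 1.36, SE 0.19, limma adjusted p = 0.353 without the block and 0.0125 with it). Gm37376 (chromosome 19, 5801941 to 5802393, plus strand) lies inside the long noncoding RNA gene Malat1 (5795690 to 5802672, minus strand). Malat1 had a log2 change of 0.66 (SE 0.20, limma adjusted p = 1.0), and reads of the 2 genes cannot be told apart unless strand was used. Each of the 3 calls ended when certain libraries were left out, while the log2 change of Esr1 stayed at 2.94 to 3.16 in those settings, that of Gm2446 at 2.71 to 2.82 and that of Gm2436 at -2.51 to -2.38. The limma adjusted p of Esr1 was 0.0909, 0.218 and 0.233 without Ctr replicates 1, 2 and 3 and 0.153 and 0.143 without KO replicates 2 and 3. That of Gm2446 was 0.0539, 0.105, 0.0552 and 0.0671 without Ctr replicates 1, 2 and 3 and KO replicate 3. That of Gm2436 was 0.122, 0.251, 0.257, 0.153 and 0.121 without Ctr replicates 1, 2 and 3 and KO replicates 2 and 3.

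**Figure D1:**
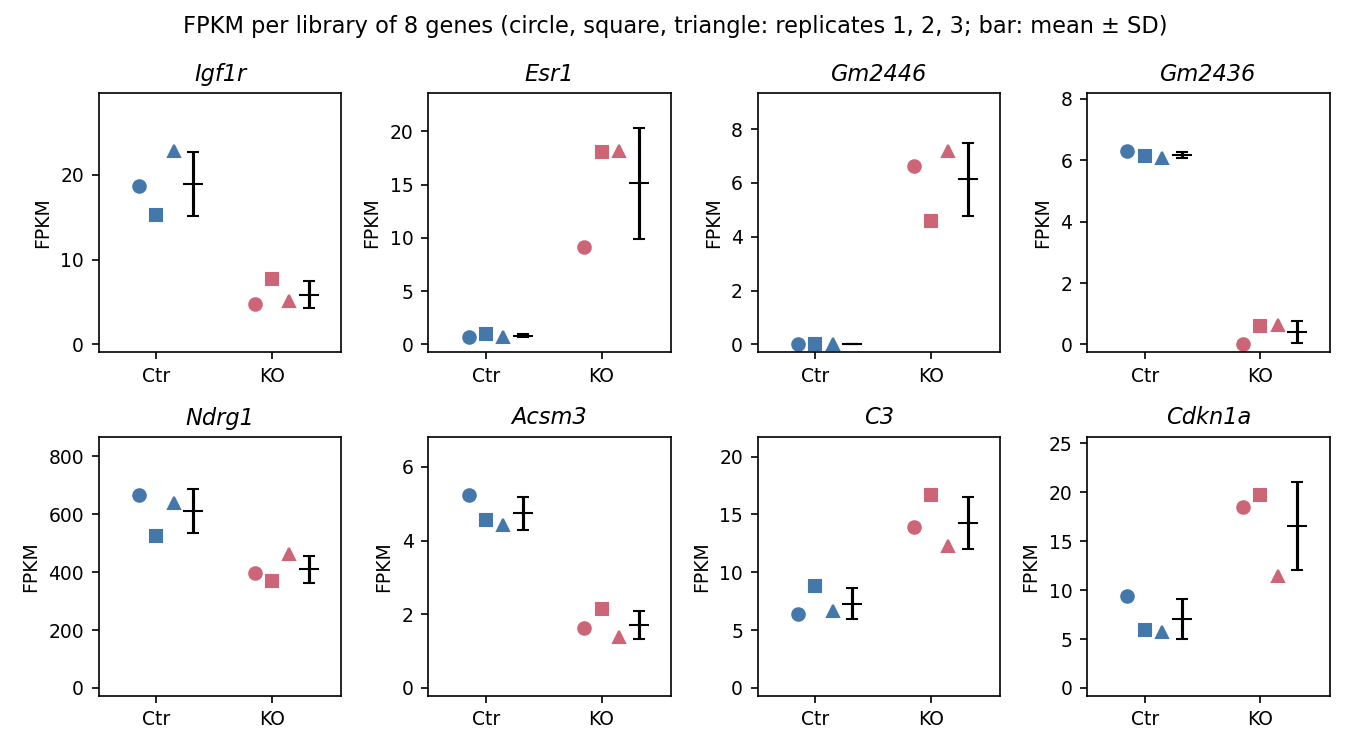
FPKM of 8 genes per library, each panel with its own vertical axis from 0, with Ctr in blue and KO in red. Circles, squares and triangles are replicates 1, 2 and 3, and the black bar is the mean ± SD of 3 libraries. Igf1r lies between 15.3 and 22.7 in Ctr and between 4.78 and 7.67 in KO. Esr1 lies between 0.72 and 0.98 in Ctr and between 9.14 and 18.1 in KO.

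The genes ranked next were not past the threshold over all genes. Values are means ± SD of FPKM with n = 3 per group, and for each of these genes all 3 KO values lay on the same side of all 3 Ctr values. Higher in KO were complement component C3 (7.28 ± 1.32 against 14.3 ± 2.23, log2 change 0.89, SE 0.15) and the cell cycle inhibitor Cdkn1a (7.0 ± 2.04 against 16.5 ± 4.50, log2 change 1.12, SE 0.24). The proteoglycan Gpc3 had a log2 change of 0.73 (SE 0.14), the acetyltransferase Crebbp 0.72 (SE 0.16) and the microRNA gene Mir1957b 1.57 (SE 0.30). Lower in KO was Acsm3, a mitochondrial medium-chain acyl-CoA synthetase (4.74 ± 0.442 against 1.71 ± 0.382, log2 change -1.09, SE 0.14). The guanylate cyclase ligand Guca2b was also lower (148 ± 33.7 against 87.6 ± 4.97, -0.73, SE 0.15). The log2 change was -0.61 (SE 0.12) for Anxa13, -0.59 (SE 0.12) for Treh, the trehalase of the brush border, and -0.54 (SE 0.11) for the membrane progestin receptor Paqr7. The limma adjusted p was 0.267 for Acsm3 and 1.0 for the others. C3 passed when adjusted over the list alone, that of NF-kappaB and cytokines (limma adjusted p = 0.0117). The large mitochondrial ribosomal RNA mt-Rnr2 had a log2 change of 0.44 (SE 0.08, limma adjusted p = 1.0).

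Genes of the late proximal tubule, organic solute transport, fatty acid oxidation and peroxisomes had lower estimates in KO as groups, by small amounts. Of the 10 splits of the 6 libraries into 3 and 3, 8 called at least as many lists as the 14 of the real split. A list call therefore does not on its own show a difference between KO and Ctr, here or in the lists that follow. Of the genes of the late proximal tubule (segment S3), 17 of 17 had a lower estimate (median log2 change -0.28, SD over genes 0.18). Among them were the brush border amino acid transporter Slc6a18 (140 ± 14.0 against 109 ± 10.9) and Acy3 (236 ± 50.8 against 169 ± 6.11, SD, n = 3 each). The S3 list fell by limma's camera at the preset correlation (adjusted p = 7.01e-05, and adjusted p = 0.747 with an estimated correlation). Organic solute and drug transporters fell in the same test (21 of 23 genes lower, median -0.17, SD 0.18, adjusted p = 7.01e-05, and adjusted p = 0.545 with an estimated correlation). Slco1a6 had a log2 change of -0.50 (SE 0.14), Slc17a3 -0.51 (SE 0.16) and Slc22a2 -0.30 (SE 0.11). Slc22a6, the basolateral organic anion transporter, was at -0.38 (SE 0.15). Genes of fatty acid oxidation and PPAR alpha targets fell (31 of 35 lower, median -0.20, SD 0.16, adjusted p = 3.51e-05, and adjusted p = 0.829 with an estimated correlation). In this list Cyp4a10 was at 371 ± 93.1 against 275 ± 10.9 and Cyp4a14 at 392 ± 75.0 against 317 ± 15.6 (SD, n = 3 each). Acot12 had a log2 change of -0.28 (SE 0.14). Peroxisome genes fell too (28 of 35 lower, median -0.07, SD 0.13, adjusted p = 0.00115, and adjusted p = 0.545 with an estimated correlation). Hao2 was at -0.43 (SE 0.11), Pecr at -0.22 (SE 0.08) and the transporter Abcd3 at -0.41 (SE 0.18). In each of the 4 lists limma passed 0 genes over all genes and 0 adjusted over the list alone, with 3, 4, 0 and 2 genes, in the order given, at an unadjusted p under 0.05.

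On average over the libraries, the lists of S3 and of fatty acid oxidation also differed between those numbered 1 and the rest (median log2 differences of -0.34 and -0.22), as did organic solute transport (-0.13). The S3 list deviated by -0.17, 0.29 and 0.30 in Ctr replicates 1, 2 and 3 and by -0.23, -0.01 and -0.19 in KO replicates 1, 2 and 3. Fatty acid oxidation deviated by -0.18, 0.26 and 0.20 in Ctr and by -0.12, -0.13 and -0.02 in KO. The S3 median was -0.44, -0.14 and -0.09 without Ctr replicates 1, 2 and 3 and -0.17 without KO replicate 1. The medians of solute transport and of peroxisome genes were -0.10 and -0.04 without Ctr replicate 3, which ended the call of peroxisome genes (camera adjusted p = 0.114). The median of fatty acid oxidation was -0.36 without Ctr replicate 1. Its call ended without Ctr replicate 2 (-0.07, adjusted p = 0.0941) and without Ctr replicate 3 (-0.13, adjusted p = 0.0556).

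Genes with sex-biased expression in the mouse kidney had mostly lower estimates in KO for both directions of the bias. Of the male-biased genes, 18 of 19 had a lower estimate (median log2 change -0.29, SD 0.35). As fixed, the male-biased list shares Slco1a1, Cyp4b1, Cyp7b1, Slc7a13 and Serpina1f with that of S3. It also shares Slco1a1 and Slc22a12 with solute transport, Nudt19 with peroxisomes and Cyp4a12a with fatty acid oxidation. The S3 list in turn shares Slc22a7, Slc22a13 and Slco1a1 with solute transport and Slc27a2 with fatty acid oxidation. The falls of these lists are therefore not independent. Beside Acsm3 the carboxylesterase Ces1f was at 26.7 ± 7.73 against 12.2 ± 3.65 (SD, n = 3 each, log2 change -1.07, SE 0.26). Slc22a28 was at -0.64 (SE 0.20) and Cyp4b1 at -0.76 (SE 0.24). The male-biased list fell by limma's camera (adjusted p = 8.03e-08, and adjusted p = 0.545 with an estimated correlation). In it 0 genes passed over all genes (5 at an unadjusted p under 0.05), and Acsm3 and Ces1f passed adjusted over the list alone (limma adjusted p = 0.00199 and 0.0384). The female-biased list fell as well (17 of 21 lower, median -0.19, SD 0.26, camera adjusted p = 0.00304, and adjusted p = 0.619 with an estimated correlation). The prolactin receptor Prlr was at -0.32 (SE 0.11) and the glutathione transferase Gsta4 at 0.37 (SE 0.12). The female-biased list also holds Hao2, Slco1a6, Slc17a1, Abcc3, Slc7a12, Cyp4a10 and Cyp4a14, which are members of the S3, solute transport, peroxisome and fatty acid oxidation lists above. Between the libraries numbered 1 and the rest the female-biased list differed by a median of -0.21. In it limma passed 0 genes over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. Genes of oestrogen and androgen receptor signalling did not pass as a list (camera adjusted p = 0.956, median -0.03). In it Esr1 alone passed, over all genes and adjusted over the list alone, and the steroid reductase Srd5a1 had a log2 change of 0.26 (SE 0.09). Between the libraries numbered 1 and the rest the male-biased list differed by -0.11. The male-biased median was -0.19 without Ctr replicate 3 and the female-biased one -0.34 without Ctr replicate 1. The female-biased call ended without Ctr replicate 2 (adjusted p = 0.122), Ctr replicate 3 (-0.11, adjusted p = 0.0556) or KO replicate 2 (adjusted p = 0.0534).

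Ribosomal protein genes and genes of the respiratory chain had mostly higher estimates in KO. Of the genes of cytosolic ribosomal proteins 81 of 84 had a higher estimate (median log2 change 0.17, SD 0.08). Examples were Rps12 (423 ± 22.4 against 500 ± 5.84), Rpl26 (512 ± 8.0 against 595 ± 36.0) and Rps16 (378 ± 21.6 against 437 ± 18.0, SD, n = 3 each). The list rose by limma's camera (adjusted p = 5.30e-37, and adjusted p = 0.545 with an estimated correlation). Its median deviation was 0.18, 0.04 and 0.02 in KO replicates 1, 2 and 3 and -0.03, -0.05 and -0.16 in Ctr replicates 1, 2 and 3. Nuclear genes of the respiratory chain and ATP synthase rose (51 of 58 higher, median 0.07, SD 0.05, adjusted p = 5.36e-08, and adjusted p = 0.747 with an estimated correlation). Atp5g1 was at 0.21 (SE 0.08), Cox8a at 0.12 (SE 0.07) and Uqcrh at 0.13 (SE 0.07). The mitochondrially encoded genes rose in the same test (13 of 13 higher, median 0.12, SD 0.04, adjusted p = 4.74e-04, and adjusted p = 0.785 with an estimated correlation). In this list mt-Nd4l was at 2632 ± 367 against 2933 ± 77.8 (SD, n = 3 each). In each of the 3 lists limma passed 0 genes over all genes and 0 adjusted over the list alone, with 19, 1 and 0 genes at an unadjusted p under 0.05. Transcripts of up to 1000 bases other than those of ribosomal proteins had a median log2 change of 0.06. With the trend with transcript length removed the respiratory chain median was 0.04, and the list still passed by camera. It was 0.03 without KO replicate 1, and the call ended without both libraries numbered 1 (adjusted p = 0.233). The mitochondrially encoded median was 0.21 without Ctr replicate 2, and quantile normalization took it to 0 (adjusted p = 0.806). Quantile normalization gives equal ranks equal values in every library. It can thus remove a shift shared by very abundant genes, so this loss decides little about KO against Ctr. The call of mitochondrially encoded genes also ended without Ctr replicate 3 (0.01, adjusted p = 0.366), without both libraries numbered 1 (adjusted p = 0.0529) and with no filter on low values (adjusted p = 0.306).

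Genes of cholesterol synthesis, the cell cycle, p53 and NF-kappaB had mostly higher estimates in KO. Cholesterol synthesis genes rose (21 of 24 higher, median 0.18, SD 0.15, camera adjusted p = 2.26e-06, and adjusted p = 0.545 with an estimated correlation). Among them were the oxidase Msmo1 (15.3 ± 2.42 against 21.7 ± 5.38), the squalene synthase Fdft1 (13.1 ± 0.681 against 17.3 ± 3.92) and Ebp (55.2 ± 2.51 against 63.4 ± 4.3, SD, n = 3 each). Cell cycle genes rose (17 of 21 higher, median 0.13, SD 0.20, adjusted p = 4.21e-04, and adjusted p = 0.545 with an estimated correlation). The cyclin gene Ccnd1 was at 60.8 ± 4.21 against 77.6 ± 7.09 (SD, n = 3 each), Cdk4 had a log2 change of 0.16 (SE 0.07) and Cdc20 one of 0.47 (SE 0.20). Genes of p53 and senescence rose (16 of 24 higher, median 0.05, SD 0.27, adjusted p = 0.00642, and adjusted p = 0.545 with an estimated correlation). Beside Cdkn1a, Phlda3 was at 2.26 ± 0.539 against 3.97 ± 0.514 (SD, n = 3 each), Ccng1 at a log2 change of 0.18 (SE 0.08) and Gdf15 at 0.37 (SE 0.20). Genes of NF-kappaB and cytokines rose (15 of 21 higher, median 0.07, SD 0.23, adjusted p = 0.0345, and adjusted p = 0.545 with an estimated correlation). Beside C3, Nfkb2 was at 0.20 (SE 0.11) and Cxcl1 at 0.42 (SE 0.21). In each of the 4 lists limma passed 0 genes over all genes (4, 2, 2 and 1 at an unadjusted p under 0.05), and C3 was the only one to pass adjusted over the list alone.

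The medians of cholesterol synthesis and of the cell cycle were 0.09 and 0.07 without KO replicate 2, and that of cholesterol synthesis was 0.29 without both libraries numbered 1. Cholesterol synthesis deviated by 0, -0.10 and -0.15 in Ctr replicates 1, 2 and 3 and by -0.08, 0.26 and 0.11 in KO replicates 1, 2 and 3, so in the libraries numbered 1 KO was not above Ctr. The cell cycle call ended without Ctr replicate 3 (0.08, camera adjusted p = 0.0556). The p53 median was 0.09, 0.03 and 0.08 without Ctr replicate 1, Ctr replicate 3 and KO replicate 1 and 0.08 with the length trend removed, and its call ended at a mean FPKM of at least 5 (adjusted p = 0.0910). The NF-kappaB call ended without Ctr replicate 3 (0.03, adjusted p = 0.209), KO replicate 2 (0.11, adjusted p = 0.0673) or KO replicate 3 (adjusted p = 0.0765). It also ended with no filter on low values (0.02, adjusted p = 0.360).

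**Figure D2:**
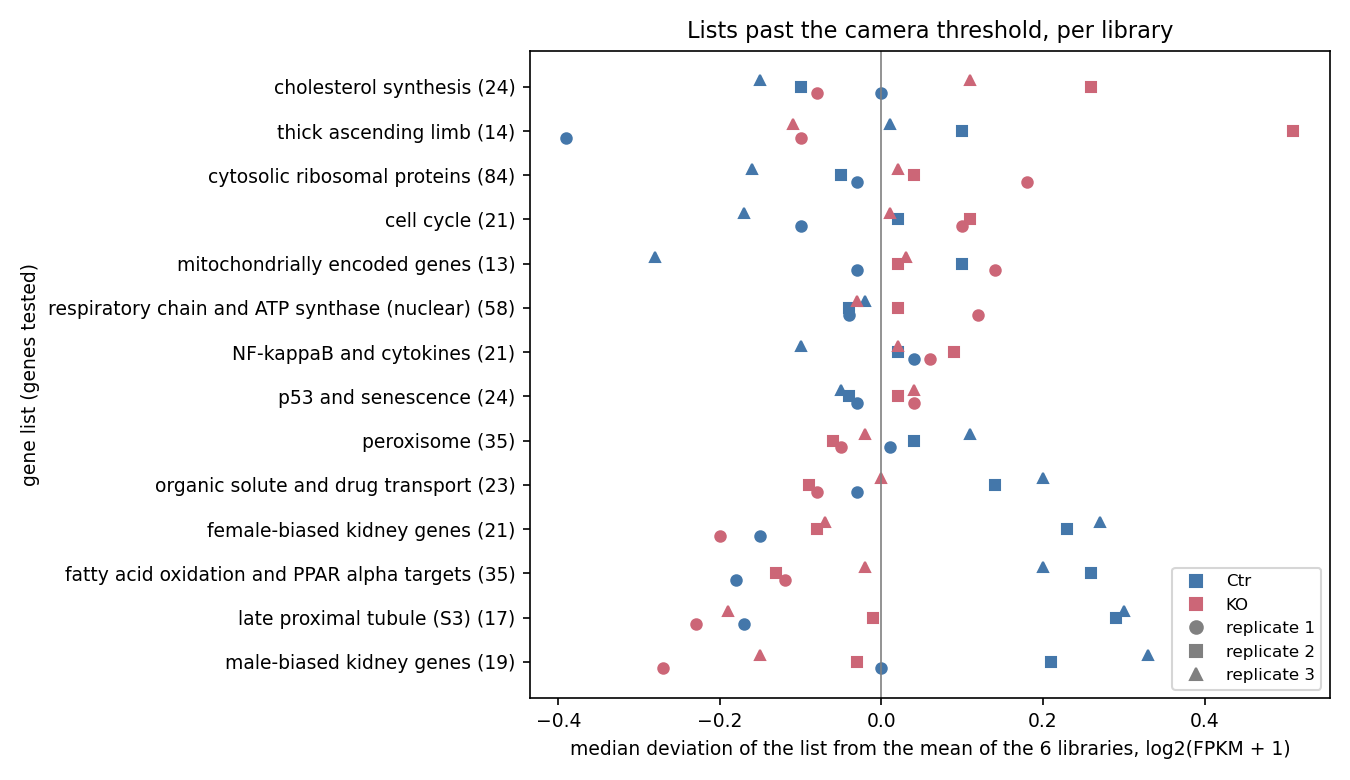
Median deviation of each of the 14 lists past the camera threshold from the mean of the 6 libraries, on the log2(FPKM + 1) scale, 1 point per library. Ctr is blue and KO red, with circle, square and triangle for replicates 1, 2 and 3 and tested genes in brackets. For ribosomal proteins the KO libraries lie at 0.18, 0.04 and 0.02 and the Ctr libraries at -0.03, -0.05 and -0.16. For the thick ascending limb KO replicate 2 lies at 0.51 and Ctr replicate 1 at -0.39.

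The lists of Igf1r signalling and of FOXO targets, the genes that insulin-like signalling holds down, did not pass. In insulin-like growth factor and insulin signalling (camera adjusted p = 0.322, median log2 change -0.05, 37 genes) Igf1r was the only gene to pass adjusted over the list alone. The insulin receptor Insr had a log2 change of -0.24 (SE 0.10), the kinase subunit Pik3ca -0.29 (SE 0.10) and Rps6kb1 0.25 (SE 0.10). FOXO target genes had a median of 0.00 (adjusted p = 0.984, 29 genes), with Bcl2l11 at -0.30 (SE 0.16) and Klf15 at 0.18 (SE 0.14). The hypoxia response list did not pass (adjusted p = 0.165, median -0.05, 21 genes), but 3 of its genes did adjusted over the list alone, in both directions (limma adjusted p = 0.0308 each). Ndrg1 was at 610 ± 75.3 in Ctr and 409 ± 47.4 in KO, Egln3 at 6.01 ± 0.205 and 4.05 ± 0.548, and Car9 at 2.68 ± 0.385 and 4.56 ± 0.765 (SD, n = 3 each). The fall of Ndrg1 need not be a hypoxia response. A known inducible driver is placed in that gene (see Other observations), though the labels name no driver. Vitamin D and phosphate handling did not pass (adjusted p = 0.0842, median -0.06, 19 genes). That list did pass with no filter on low values, quantile normalization or library weights, and without Ctr replicate 2 or KO replicate 3. In it the vitamin D hydroxylase Cyp24a1 was at 93.1 ± 24.5 against 49.8 ± 8.17 (SD, n = 3 each). The vitamin D receptor Vdr had a log2 change of -0.28 (SE 0.09) and the binding protein Gc 0.40 (SE 0.14). Of this list limma passed 0 genes over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The replicate block brought early proximal tubule (median -0.08) past the threshold (camera adjusted p = 0.126 without the block and 0.0391 with it, and adjusted p = 0.763 with an estimated correlation). Its genes Miox, Hnf4a and Lrp2 were at -0.13 (SE 0.07), -0.15 (SE 0.12) and -0.15 (SE 0.14). Glycolysis (median 0.05) passed with the block too (adjusted p = 0.0842 without and 0.0393 with it, and adjusted p = 0.793 with an estimated correlation), with Aldoc at 0.53 (SE 0.14). With the block and an estimated correlation 0 lists passed.

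The other lists of metabolism and stress did not pass by camera in the main fit, though several did with 1 library left out. Tubular injury and repair had a median of 0.04 (adjusted p = 0.0842), with Il34 at 0.45 (SE 0.14). That list passed when scaled to the same sum and without Ctr replicate 1 or KO replicate 3. Gluconeogenesis had a median of 0.01 (adjusted p = 0.769), with Pck1 at -0.26 (SE 0.28). For fatty acid and triglyceride synthesis it was -0.06 (adjusted p = 0.476), with Fads1 at 0.29 (SE 0.12). Medians were -0.04 for amino acid metabolism (adjusted p = 0.398), -0.02 for the citric acid cycle (0.576) and -0.02 for mitochondrial biogenesis (0.769). They were -0.03 for autophagy and lysosome (adjusted p = 0.550), -0.03 for the integrated stress and unfolded protein responses (0.769) and 0.02 for NRF2 targets and glutathione (0.732). For apoptosis and ferroptosis and for extracellular matrix and TGF beta they were -0.01 (adjusted p = 0.963 and 0.984). The interferon response had a median of 0.02 (adjusted p = 0.939), with Irf7 at -0.25 (SE 0.15). Immediate early genes (0.02, adjusted p = 0.721) and heat shock genes (-0.03, adjusted p = 0.732), which rise during tissue dissociation, did not pass either. Camera sets a list against all other genes, and the median log2 change of all genes was -0.02. For the lists of extracellular matrix, of oestrogen and androgen receptors and of the distal tubule the direction of the test was up while the median was below 0. For gluconeogenesis, the interferon response and FOXO targets the median was above 0 and the mean below it.

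Podocyte, endothelial and red blood cell transcripts were abundant in the libraries numbered 1 of both groups and low in the other 4. The podocyte gene Podxl was at 125.7 and 96.1 FPKM in Ctr replicate 1 and KO replicate 1 and at 5.0 to 9.19 elsewhere. The endothelial gene Kdr was at 26.6 and 19.3 against 0.87 to 1.23, and the haemoglobin gene Hbb-bs at 134 and 64.8 against 0.17 to 1.56. Over whole lists the libraries numbered 1 exceeded the rest by median log2 differences of 3.11 (podocytes), 3.40 (erythroid cells) and 1.86 (endothelium). The difference was 0.63 for fibroblasts, pericytes and smooth muscle, 0.40 for myeloid cells, -0.41 for the thick ascending limb and -0.48 for intercalated cells. Immediate early genes, which rise during tissue dissociation, differed by a median of -0.41, with Atf3 at 84.9 and 52.9 FPKM in Ctr replicate 1 and KO replicate 1 and at 140.6 to 203 elsewhere. Every library, whatever its number, also held transcripts of other tubule segments. Umod of the thick ascending limb lay at 1077 to 2300 FPKM and Slc12a3 of the distal convoluted tubule at 364 to 545. Aqp2 of principal cells lay at 111 to 281, and the proximal tubule gene Miox at 2365 to 2748.

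Between KO and Ctr most lists of other cell types did not pass by camera with all 6 libraries. Podocytes passed without Ctr replicate 1 or KO replicate 1, fibroblasts, pericytes and smooth muscle without KO replicate 1. Intercalated cells passed without Ctr replicate 1, Ctr replicate 2 or KO replicate 1 and with library weights. Principal cells passed without Ctr replicate 1 or 2, distal tubule without KO replicate 3, and endothelium without Ctr replicate 1, Ctr replicate 3 or KO replicate 1. Leaving out 1 of the libraries numbered 1 keeps the other in only 1 group. The podocyte list deviated by 2.22 in Ctr replicate 1, 1.89 in KO replicate 1 and -1.11 to -0.87 in the rest. Passes in those settings therefore do not on their own show a difference between KO and Ctr. Podocytes had a median log2 change of -0.08 (adjusted p = 0.956), erythroid cells -0.21 (0.762), fibroblasts, pericytes and smooth muscle -0.04 (0.956) and myeloid cells 0.01 (0.762). Intercalated cells had a median of 0.05 (adjusted p = 0.374), collecting duct principal cells 0.05 (0.721), and thin limb and parietal epithelium 0.04 (0.374). Distal convoluted and connecting tubule had one of -0.02 (adjusted p = 0.322), with Slc12a3 at 0.27 (SE 0.11). Endothelium had a median of -0.23 (adjusted p = 0.684), and it passed with the replicate block (adjusted p = 5.92e-06, and adjusted p = 0.556 with an estimated correlation). The thick ascending limb list rose in KO (10 of 14 genes higher, median 0.17, SD 0.17, adjusted p = 0.0435, and adjusted p = 0.979 with an estimated correlation). In it Cldn19 was at 0.41 (SE 0.25) and Wfdc15b at 0.30 (SE 0.21). Limma passed 0 of its genes over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05. Its median was 0.05 without Ctr replicate 1 (adjusted p = 0.881) and -0.05 without KO replicate 2 (adjusted p = 0.734), and the call ended without both libraries numbered 1 (0.08, adjusted p = 0.247). It also ended with no filter on low values (adjusted p = 0.144), scaling by the median ratio (0.0545), quantile normalization (0.0501), limma without the trend (0.0549) and the length trend removed (0.112). Without both libraries numbered 1, limma called 4 genes higher (Esr1, Gm2446, Gm37376 and Snord83b) and 2 lower (Gm2436 and Gm6293). There 11 of the 14 lists kept their direction and call.

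**Figure D3:**
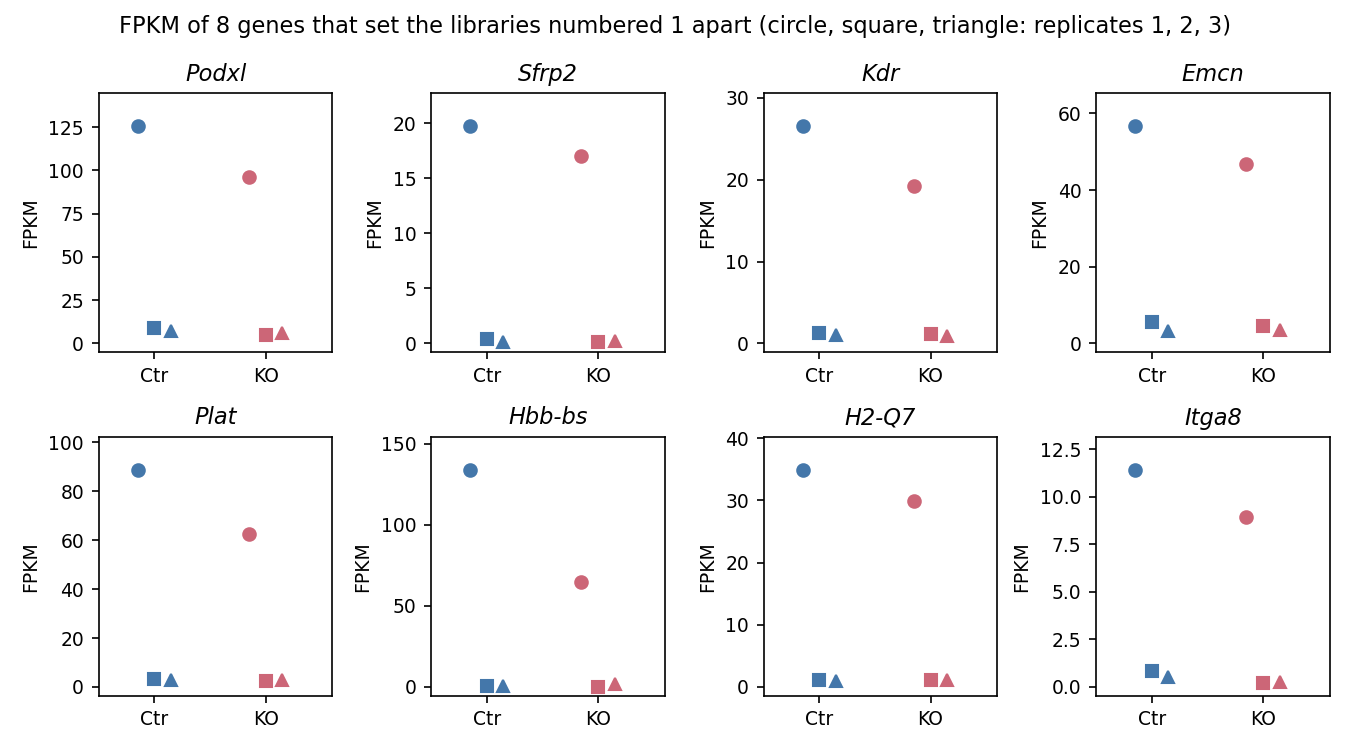
FPKM per library of 8 genes that set the libraries numbered 1 apart, each panel with its own vertical axis from 0, with Ctr in blue and KO in red. Circles, squares and triangles are replicates 1, 2 and 3. The circles of both groups stand apart from the other points, as for Podxl at 125.7 and 96.1 FPKM against 5.0 to 9.19.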

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

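The settings that leave out both libraries numbered 1, that set these against the rest, that remove the trend with transcript length, and that combine the block with an estimated correlation were chosen after the data had been seen. The other settings were fixed before. Igf1r kept its direction and stayed outside the threshold in all 20 alternatives (log2 change -1.73 to -1.14, limma adjusted p 0.138 to 1.0). Esr1 kept its direction in 20 and passed in 13 (log2 change 1.75 to 4.0, adjusted p 0.00168 to 0.233). Against 2 genes higher in KO, 1 was called with a pseudocount of 5, with no filter and with a mean FPKM of at least 5, and 4 without both libraries numbered 1. Against 1 gene lower, 0 were called with a pseudocount of 0.1, a mean FPKM of at least 5, quantile normalization and the length trend removed, and 2 with no filter and without both libraries numbered 1. Leaving out 1 library gave 0 to 3 genes higher and 0 to 1 lower. The cause of these moves was not tested. Of the 14 lists, 0 passed by camera with an estimated correlation (3 had an unadjusted p under 0.05), and 0 with the replicate block and an estimated correlation. By fry 0 passed on balance in a direction and 2 for change in either direction, male-biased genes and oestrogen and androgen receptor signalling. The receptor list had a median log2 change of -0.03 (SD over genes 0.82), and Esr1 was its only gene past the threshold. A pass of that list by fry can therefore rest on Esr1 alone, with or without the block. Leaving out 1 library gave 11 to 19 lists, and ribosomal proteins, male-biased genes, cholesterol synthesis, solute transport and S3 passed in every setting that kept the preset correlation of 0.01. The median of the thick ascending limb list was -0.046 to 0.258 with 1 library left out, below 0 without KO replicate 2. With the replicate block 3 genes were higher, 1 was lower and 17 lists passed, adding Gm37376 among genes and early proximal tubule, glycolysis and endothelium among camera's lists. By fry for change in either direction 3 lists passed with the block, p53, NF-kappaB and oestrogen and androgen receptor signalling, and male-biased genes did not (adjusted p = 0.121). Of the 92 genes the naming rule took that are not printed, 26 changed sign under some alternative and 0 passed the threshold under any. The libraries held about 10000000 to 12800000 fragments. In data simulated with the spread of the fit without the block, 1.5-fold changes were recovered for 47.8% of genes. With the spread of the blocked fit the share was 77.9%, also tested without the block, so it is not a rate of the blocked test. These rates hold for 200 changed genes, beside a list of 30 moved by 0.3, among genes drawn independently. In the data themselves Igf1r (3.24-fold lower) did not pass over all genes, so larger changes of single genes could be missed too.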

Other observations

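All tests of explanations below were chosen after the results had been seen, except the splits of the libraries for the counts of genes and lists.

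The libraries numbered 1 of both groups also carried transcripts of mesangial and vascular cells, a description that rests on genes picked because they set these libraries apart. The mesangial integrin Itga8 was at 11.4 FPKM in Ctr replicate 1 and 8.93 in KO replicate 1 and at 0.20 to 0.82 in the other 4 libraries. The secreted Wnt antagonist Sfrp2 was at 19.7 and 17.0 against 0.11 to 0.38, and the plasminogen activator Plat at 88.8 and 62.3 against 2.41 to 3.17. The class I histocompatibility genes H2-Q7 (35.0 and 29.9 against 1.0 to 1.11) and H2-Q6 (48.4 and 41.2 against 1.36 to 1.98) stood apart in the same libraries, although near-identical family members share reads. These genes and Hbb-bs were higher in Ctr replicate 1 than in KO replicate 1, while the list of fibroblasts, pericytes and smooth muscle (median deviations of 0.23 and 0.60) and that of myeloid cells (0.14 and 0.50) were higher in KO replicate 1.

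Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 3 genes past the threshold, and the highest of the others gave 2. For lists, 8 of the 10 gave at least the 14 of the real split, and the highest of the others gave 24. That split set Ctr replicate 1, KO replicate 1 and KO replicate 2 against the rest. With 10 splits no share can fall under 0.05. The 4 splits that keep both libraries numbered 1 together gave 18 to 24 lists. The 3 others that part all 3 numbered pairs gave 9, 14 and 14 lists and 0 genes, so for lists the real split (14) did not stand out among them.

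Esr1 was 18.6-fold higher in KO, and its levels were 9.14, 18.1 and 18.1 FPKM in KO replicates 1, 2 and 3. Against cells of another listed type as the source stands that the highest median log2 change among the 10 lists of other cell types was 0.17 (thick ascending limb), far below the lower bound of 2.51 of the Esr1 interval. A candidate explanation is a Cre recombinase fused to a ligand-binding domain of the oestrogen receptor, whose reads could be assigned to Esr1. The labels do not name the driver, and Ndrg1, which would lose up to 1 allele in a known inducible driver placed in that gene, had a log2 change of -0.57 (95% interval -0.86 to -0.29), a value that other causes could give too. A response of the gene itself (log2 change 3.10) cannot be told apart from this, because driver and deletion come together in the KO mice.

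The exchange between Gm2446 and Gm2436 in KO is consistent with reads of near-identical copies being assigned to either copy. The log2 change of their summed FPKM was 0.055 (SE 0.15), under the 0.5 set as the bound, while each copy alone moved by more than 2 in opposite directions. All 3 KO libraries show the exchange, so a difference of strain background between the groups near this locus may also be involved, which these data do not test.

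The ribosomal protein list was higher in KO by a median of 0.17, and across the 11475 protein-coding genes the log2 change fell with transcript length (Spearman's rho -0.27 across genes, which are not independent replicates), mostly through KO replicate 1 (rho -0.38 for its deviations), and ribosomal protein transcripts are short. Length was that of each gene's longest annotated transcript. With the length trend removed the median was 0.14, which argues against length, so measured, as the whole cause. Without KO replicate 1, where rho across genes was -0.05, the median was 0.12. Both medians lay above the highest of 1000 expression-matched random lists (0.03 each). Random lists lack the shared variation of this list (estimated correlation 0.562), so they cannot decide whether it differs between KO and Ctr. Variation of the whole list between libraries, whatever their group, stays open: 1 of the 10 splits, the real one, gave a median difference as large, and the highest of the others was 0.12. A response of ribosome synthesis to the loss of Igf1r stays open as well, as an untested biological explanation.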
